A study of Mus musculus with 12 samples.

How the data were processed

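RNA was measured in 12 libraries of mouse primary cortical neurons from embryonic day 16 Swiss Webster embryos. Per the labels, the neurons were infected with lentivirus at 5 days in vitro and RNA was taken at 10 days in vitro, after removal of ribosomal RNA. There were 3 groups of 4 libraries: a control vector, exon 1 of huntingtin with 25 glutamines (Htt-25Q, the length in the normal range) and exon 1 with 72 glutamines (Htt-72Q, a length in the range of Huntington disease). The infection label reads 'Empty vector' for 3 control libraries and 'Control vector' for control vector 2, which was placed by its title. Each library is named by its group and the number in its title. The description of each library also begins with a preparation number (22, 24, 26, 27 or 27_1), whose meaning the labels do not state.

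The submitters' processing notes name STAR 2.0.4b, Subread and featureCounts 1.45 and the genome build GRCm38, with no roles or settings. Strandedness, the handling of reads that map to several places and the annotation release are not given in the sources used here. The deposited file of each library holds counts of reads for 41388 genes, of which 40254 have a symbol in the names table of the reference annotation. Beside the counts, the authors gave CPM (counts scaled to the library total) and RPKM (CPM per kilobase). In 12 of the 12 libraries the deposited CPM and RPKM columns follow from the counts, with differences of at most 5.09e-10 and 5.09e-11, so the counts alone were used. Chromosome positions were taken from GENCODE M21 on GRCm38. No 2 libraries were duplicates: the smallest chi-square per degree of freedom between any pair of libraries was 9.00.

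Differential expression was tested with the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts, with TMM scaling, the filterByExpr filter at its minimum count of 10 and 1 fit of all 12 libraries on the 3 groups. It leaves 9 residual degrees of freedom and tested 14707 genes. Genes with a two-sided Benjamini-Hochberg adjusted p under 0.05 are called. Log2 fold changes are those of this fit, each with its SE and 4 libraries per group, and levels are TMM-scaled CPM as mean ± SD over 4 libraries unless stated. On simulated counts with planted changes in Htt-72Q, the test against control vector recovered 15.4% of genes changed 1.5-fold, 47.0% of those changed 2-fold and 96.8% of those changed 4-fold, with 4 false calls among 106. With planted changes in Htt-25Q the shares against control vector were 15.4%, 60.6% and 90.8%, with 2 false calls among 111. The simulated counts were independent between genes and libraries, and few genes were changed. They held no likeness between libraries of 1 preparation, so these shares need not hold for the real libraries.

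Lists of genes were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the tested lists, with an estimated correlation and with fry beside it. The neuronal lists cover immediate early genes, striatal and Huntington-sensitive signalling genes, REST targets, glutamate receptors, postsynaptic density genes, synaptic vesicle release, GABA receptors, voltage-gated ion channels and neuropeptides. The stress and metabolism lists cover heat shock, the unfolded protein and integrated stress response, proteasome, autophagy and lysosome, respiratory chain, mitochondrial messenger RNAs, mitochondrial import, cholesterol synthesis, p53 targets, type I interferon and NF-kB. The others are Hox and other Polycomb-target developmental genes, ribosomal proteins, 10 sets of cell markers, long non-coding RNAs and HTT-interacting genes. Lists with fewer than 5 tested members were given only as counts from a fit without the filter. Beside counts of called members over all genes tested, counts adjusted over the list alone are given. The lists, comparisons, tests, rule for named genes and alternatives named here were fixed before the data were examined.

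Named genes follow that rule for each comparison. They are Htt, and the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change among genes with a symbol and a mean of at least 1 CPM. Predicted genes and pseudogenes are skipped. They are also at most 4 called members with the smallest p in each list. Where fewer than 5 genes were called, the 5 with the smallest p that meet the CPM minimum are given as values. Genes named outside this rule are said to be so where they appear. Some genes that were tested are not reported here by name, and the list counts include them.

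The alternatives were DESeq2 1.42.0, limma voom, other scaling factors, other filters, other thresholds, fits of only the 2 groups compared, blocks by title number or by preparation, a surrogate variable (sva 3.50.0) and leaving out each library in turn. Residuals of libraries with the same preparation number correlated across genes (10 of 10 pairs above 0.1, median r 0.28), which the blocks by preparation take into account. Libraries that share a title number did not always do so (lowest r -0.49). Because both comparisons against control vector use the same libraries, their shared part was set against simulated groups without changes and against fits that gave each comparison 2 of the 4 control libraries. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Total counts per library ranged from 12.4 M to 27.5 M.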

Results

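Gene counts were collected from 12 cortical neuron cultures, 4 per group. Total counts were 23.4 M, 16.8 M, 20.6 M and 12.7 M in control vector 1 to 4. They were 23.1 M, 21.4 M, 27.5 M and 18.1 M in Htt-25Q 1 to 4, and 14.6 M, 13.9 M, 12.4 M and 20.04 M in Htt-72Q 1 to 4. The group means were 18.4 ± 4.66 M (SD, n = 4), 22.5 ± 3.90 M and 15.2 ± 3.32 M. The mitochondrial ribosomal RNA gene mt-Rnr2 took the most counts in each of the 12 libraries. Mitochondrial ribosomal RNAs together held 8.98 ± 3.54% of counts in control vector, 10.7 ± 2.34% in Htt-25Q and 13.1 ± 1.83% in Htt-72Q (SD, n = 4 each).

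The libraries also fell into a pair of classes of 6 that cross the groups, drawn at the largest gap between libraries in log2 CPM of Ctnnd1. The labels used here name no such classes, so whether their origin is technical is not known. Gapdh lay at 9.16 to 20.3 CPM of the library total in class A and at 35.4 to 50.2 CPM in class B. The mitochondrial gene mt-Nd2 lay at 252 to 377 CPM in class A and 71.4 to 164 CPM in class B. Class B held 3 of the 4 Htt-72Q libraries, 2 control libraries and 1 Htt-25Q library. With group in the model the class itself called 12 genes. The principal component with the most variance (42.4%) separated the Htt-72Q libraries from the other 8.

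**Figure D1:**
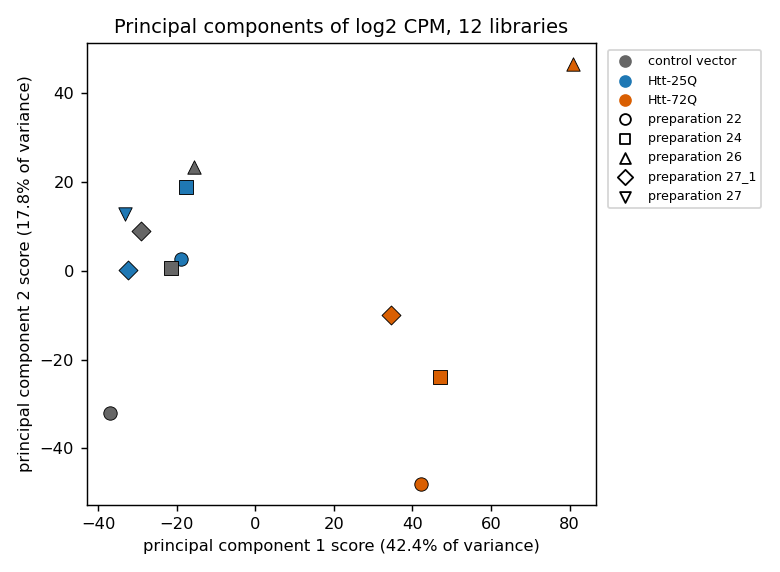
Principal components of log2 CPM of the tested genes, with each point a library, coloured by group and shaped by preparation number, and the axes in component scores. The 4 Htt-72Q libraries lie apart from the other 8 on the component with 42.4% of the variance.

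The mouse gene Htt (ENSMUSG00000029104, GRCm38 chromosome 5, 34761740 to 34912534, plus strand) is the gene named by the design. The constructs hold only its exon 1, and whether their sequence is mouse or human is not stated, so the count checks the constructs only if their reads can align to the mouse gene. Htt stood at 168 ± 36.0 CPM in Htt-72Q, 148 ± 27.0 CPM in Htt-25Q and 143 ± 63.9 CPM in control vector (SD, n = 4 each), differences smaller than the spread between libraries. The log2 fold change was 0.24 ± 0.25 for Htt-72Q against control vector (adjusted p = 0.529, edgeR quasi-likelihood test). It was 0.053 ± 0.25 for Htt-25Q against control vector (adjusted p = 1) and 0.19 ± 0.25 for Htt-72Q against Htt-25Q (adjusted p = 0.643). Without control vector 1, the first was 0.59 with an adjusted p of 0.0376.

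Htt-72Q against control vector asks what the long repeat does to the neurons relative to virus alone. Many genes of excitatory synapses and of neuronal identity fell, and their lists were called lower, though not with an estimated correlation (adjusted p = 0.267 for postsynaptic density genes and adjusted p = 0.0564 for excitatory neuron markers). Gpr6, an orphan receptor gene known from striatal neurons, fell from 57.7 ± 16.2 to 2.48 ± 0.800 CPM (SD, n = 4 each), and the transcription factor Mef2c fell from 1895 ± 236 to 414 ± 46.2 CPM. Among the genes near 0 in control neurons that rose were Pou4f1, Lhx4, Isl2 and Ebf3, which encode transcription factors known from embryonic development. The p53 target and proteasome lists were called higher, but not with an estimated correlation (adjusted p = 0.0564 and adjusted p = 0.358). Of 14707 genes tested, 3411 were called, 1389 higher and 2022 lower (1735 and 1778 with upper-quartile scaling), and 1291 of them changed at least 2-fold, 412 higher and 879 lower. In 3483 genes (23.7%) the ranges of the groups did not overlap, where chance gives 2.86% with preparation ignored.

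The largest rises in Htt-72Q over control vector included Pou4f1, a POU factor of sensory and midbrain neurons, with a log2 fold change of 6.37 ± 0.50 (SE, adjusted p = 1.18e-06), from 0.124 to 9.87 CPM. Irs4, an insulin receptor substrate, rose by 6.32 ± 0.64. The LIM homeobox genes Lhx4 and Isl2, which mark motor neurons in the embryo, rose by 5.30 ± 0.48 and 3.98 ± 0.45, the transcription factor Ebf3 by 4.15 ± 0.39 and Ripk4, a kinase of epithelial differentiation, by 3.88 ± 0.49. Cdkn2a, which encodes inhibitors of the cell cycle and of p53 breakdown, rose by 4.60 ± 0.53, and by 5.24 without control vector 1. Pgr15l, a G protein-coupled receptor gene, rose by 4.64 ± 0.68, and by 5.52 without control vector 4. The largest falls besides Gpr6 (-4.54 ± 0.26, adjusted p = 9.93e-08) were St3gal1, a sialyltransferase, at -3.41 ± 0.28, and the potassium channel subunit gene Kcng1 at -3.39 ± 0.60. They included also Cd93 at -3.31 ± 0.40, Nwd2 at -3.22 ± 0.16, the fibronectin gene Fn1 at -3.19 ± 0.50, the histamine receptor gene Hrh3 at -3.18 ± 0.26 and Dock5 at -3.10 ± 0.22. Without control vector 1, Kcng1 stood at -2.18 and Fn1 at -2.31.

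Excitatory cortical neuron markers fell as a list (median log2 fold change -0.92, camera adjusted p = 2.09e-07, adjusted p = 0.0564 with an estimated correlation). Of 20 measured, 13 fell, 0 rose and 7 did not pass, and adjusted over the list alone 15 fell and 1 rose. Lmo4 (-1.79 ± 0.10), Mef2c (-2.19 ± 0.13) and Rorb (-1.48 ± 0.17), transcriptional regulators of cortical neurons, were among them. Inhibitory neuron markers also fell (median -0.57, adjusted p = 0.00236, adjusted p = 0.267 with an estimated correlation), with 9 of 21 lower, 0 higher and 12 not passing, and 9 lower adjusted over the list alone. Gad1, which makes GABA, changed by -1.33 ± 0.25. Astrocyte markers did not pass (median 0.08, with camera pointing lower, adjusted p = 0.998), with only Gpc5 of 20 called (-1.14 ± 0.14). Oligodendrocyte markers did not pass either (median -0.47, adjusted p = 0.115), except with the block by preparation (0.0246) and without Htt-72Q 3 (0.0300) or control vector 4 (0.0350). Mobp, a myelin gene, was the 1 of 16 called, at -2.89, or -3.52 without Htt-72Q 3. Neural progenitor markers had a median of 0.17 (adjusted p = 0.185), with 0 of 17 called.

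In lists of the synapse and of excitability many members fell and many others did not pass. In the postsynaptic density list 16 of 25 fell, 1 rose and 8 did not pass (adjusted over the list alone 18 and 1; adjusted p = 2.09e-07, adjusted p = 0.267 with an estimated correlation). Camk2b, a kinase of synaptic plasticity, went from 805 ± 83.2 to 242 ± 28.3 CPM (log2 fold change -1.73 ± 0.12), and Dlg2, a scaffold protein gene, changed by -1.54 ± 0.14. Of 24 glutamate receptor genes 13 fell, 1 rose and 10 did not pass (the same counts adjusted over the list alone; adjusted p = 5.06e-06, adjusted p = 0.267 with an estimated correlation). Among them were Gria1 (-1.41 ± 0.14), Gria2 (-1.09 ± 0.11) and Grm2 (-2.35 ± 0.24). Of 33 voltage-gated channel genes 18 fell, 0 rose and 15 did not pass, 21 adjusted over the list alone (adjusted p = 1.73e-08, adjusted p = 0.267 with an estimated correlation). The potassium channel genes Kcnq5 (-1.86 ± 0.13) and Kcnh1 (-2.67 ± 0.20) were among them. Of 14 GABA receptor genes 9 fell, 0 rose and 5 did not pass, 9 adjusted over the list alone (adjusted p = 0.00021, adjusted p = 0.267 with an estimated correlation), with Gabra5 at -1.93 ± 0.14. In the synaptic vesicle list 11 of 25 fell, 0 rose and 14 did not pass, 11 adjusted over the list alone (adjusted p = 0.000384, adjusted p = 0.417 with an estimated correlation). Rph3a was at -1.71 ± 0.18 and the vesicular glutamate transporter gene Slc17a7 at -1.39 ± 0.21.

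Of 25 striatal and Huntington-sensitive signalling genes 15 fell, 1 rose and 9 did not pass, 16 and 1 adjusted over the list alone (adjusted p = 4.13e-07, adjusted p = 0.172 with an estimated correlation). Arpp21 changed by -2.13 ± 0.17 and the cannabinoid receptor gene Cnr1 by -1.17 ± 0.10. Of 22 neuropeptide genes 5 fell, 0 rose and 17 did not pass, 6 adjusted over the list alone (adjusted p = 0.0144, adjusted p = 0.59 with an estimated correlation, and 0.108 without Htt-72Q 1). Cck was at -1.66 ± 0.25 and Sst at -0.98 ± 0.19. Of 25 genes of cholesterol synthesis and SREBP control 7 fell, 1 rose and 17 did not pass, 8 and 1 adjusted over the list alone. The list was called (adjusted p = 0.0152, adjusted p = 0.635 with an estimated correlation, 0.122 without Htt-72Q 1 and 0.0570 without control vector 4). Hmgcs1, an early enzyme of the pathway, changed by -0.85 ± 0.15 and Lss, a later one, by 0.56 ± 0.11. Htt-interacting genes did not move as a list (median -0.03, adjusted p = 0.602), but 4 of 21 fell and 1 rose: Hap1, whose protein binds huntingtin, rose by 1.41 ± 0.15 and Hip1r was at -1.32 ± 0.11. REST target genes did not pass either (median -0.14, adjusted p = 0.172, 6 of 23 lower and 1 higher). Long non-coding RNAs had a median of -0.14, with camera pointing higher (adjusted p = 0.703), with Miat lower at -1.14 ± 0.27 and Gas5 among 2 of 11 higher at 0.63 ± 0.15.

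The proteasome list rose: 15 of 31 subunit genes were higher, 0 lower and 16 did not pass, with 23 higher adjusted over the list alone (median 0.46, adjusted p = 3.88e-07, adjusted p = 0.358 with an estimated correlation). Psmd12 rose by 0.62 ± 0.15 and Psmd2 by 0.49 ± 0.12. Of 28 autophagy and lysosome genes 7 rose, 1 fell and 20 did not pass, 11 and 1 adjusted over the list alone (adjusted p = 0.00496, adjusted p = 0.25 with an estimated correlation). The lysosomal protease gene Ctsd went from 379 ± 69.3 to 700 ± 53.5 CPM (0.89 ± 0.13, adjusted p = 0.000242), and Sqstm1, an autophagy receptor gene, rose by 0.63 ± 0.12. In the p53 list 13 of 23 rose, 1 fell and 9 did not pass, 13 and 2 adjusted over the list alone (median 0.59, adjusted p = 0.000209, adjusted p = 0.0564 with an estimated correlation). Phlda3 rose by 2.09 ± 0.25, Perp by 1.21 ± 0.16 and Aen by 0.82 ± 0.13, while Plk2, a kinase of synapses as well as a p53 target, was at -1.04 ± 0.16. Of 9 interferon genes 3 rose, 1 fell and 5 did not pass, 4 and 1 adjusted over the list alone (median 0.67, adjusted p = 0.0174, adjusted p = 0.182 with an estimated correlation). Usp18 rose by 3.19 ± 0.55 from 0.0988 CPM. Of 24 proliferation genes 4 rose, 1 fell and 19 did not pass, 4 and 1 adjusted over the list alone (adjusted p = 0.0167, adjusted p = 0.267 with an estimated correlation, and 0.0513 without Htt-72Q 1). Tpx2, a spindle gene, was at 0.83 ± 0.19 and E2f1 at -0.95 ± 0.18. The respiratory chain list was called higher (median 0.27, adjusted p = 0.0138, adjusted p = 0.655 with an estimated correlation, 0.325 without control vector 1 and 0.0964 without Htt-72Q 3) with 0 of 36 members called.

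The remaining lists did not pass against control vector. The immediate early list had a median of -0.77 (adjusted p = 0.0573; 0.000789 with a block by preparation), with 4 of 27 lower, 1 higher and 22 not passing. It passed without control vector 1, 2 or 3, Htt-72Q 4 or any 1 Htt-25Q library (0.00357 to 0.0499), with a median of -1.45 without Htt-72Q 4. Without control vector 4 the median turned to 0.18 (0.392). Within preparations 22, 24, 26 and 27_1 the list score differed by -0.66, -0.57, -0.53 and -0.89. Inhba, which encodes an activin subunit, was at -2.55 ± 0.30. Ribosomal protein genes had a median of 0.23 (adjusted p = 0.0527, 0 of 39 called; 0.0172 with the block). They passed also without Htt-72Q 1, 2 or 4, control vector 3 or 4 or Htt-25Q 3 (0.0119 to 0.0499). Mitochondrial messenger RNAs had a median of -0.40 (0.753, 0 of 7 called). Mitochondrial import had 0.19 (0.102; 0.0283 without control vector 4), with 2 of 22 higher, among them Grpel1 at 0.77 ± 0.18. Heat shock genes had 0.09 (0.465, 2 of 23 higher and 3 lower), the unfolded protein and stress response list 0.05 (0.234, 4 of 27 higher, with Hspa5 at 0.52 ± 0.11), and NF-kB genes 0.24 (0.312, 0 of 7 called). Fibroblast and mural markers had a median of -0.66 (0.195), with 2 of 10 higher and 4 lower, among them Postn at -2.90 ± 0.39 and Igf2 at 3.39 ± 0.55. Of 16 list calls by camera, 0 held with an estimated correlation and 13 held with fry. Fry did not call neuropeptides (0.0629), respiratory chain (0.243) or cholesterol genes (0.104), and called REST targets (0.0460), NF-kB genes (0.0354) and fibroblast markers (0.00432). Leaving out 1 library ended the calls of 12 of 103 named genes, among them Scg2 (-0.79, adjusted p = 0.0704 without control vector 4) and Cdk1 (0.48, adjusted p = 0.108 without Htt-72Q 3).

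**Figure D2:**
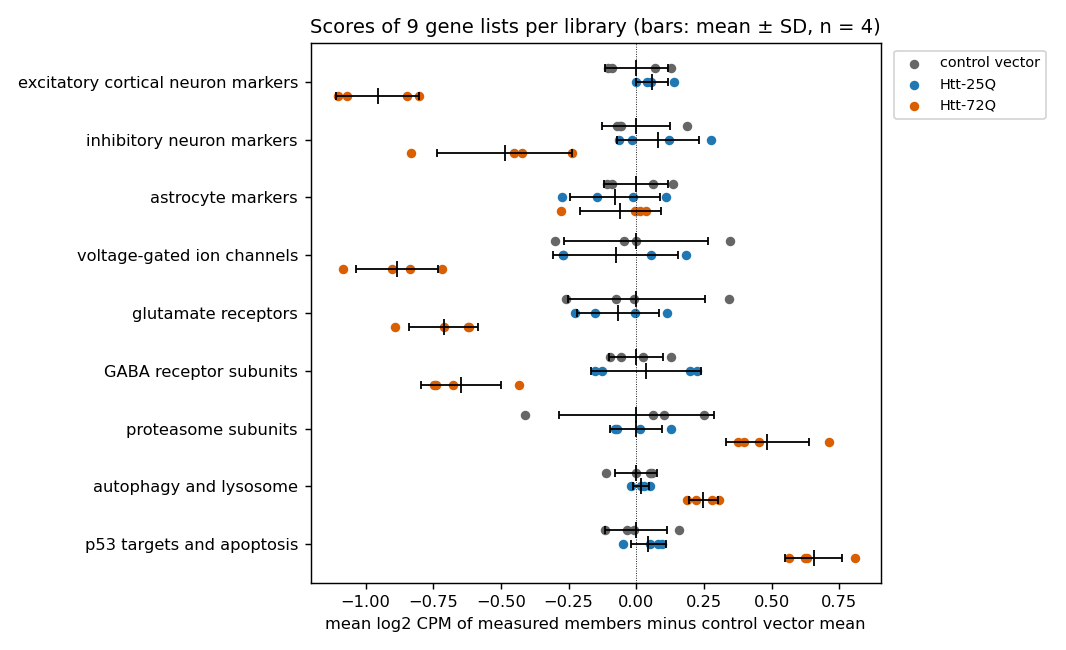
Scores of 9 gene lists per library, as mean log2 CPM of the measured members minus the control vector mean, with each point a library and bars for mean ± SD (n = 4). Excitatory neuron markers lie at -1.10 to -0.80 in the 4 Htt-72Q libraries and at -0.11 to 0.14 in the other 8.

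Htt-72Q against Htt-25Q asks what the length of the repeat does, since both groups received exon 1. The picture was close to that against control vector: the synaptic, channel and excitatory neuron lists were called lower and the p53 and proteasome lists higher. With an estimated correlation the excitatory neuron and p53 calls held (adjusted p = 0.0453 each), while those of the synaptic, channel and proteasome lists were lost (adjusted p = 0.349 to 0.547), and many of their members did not pass. The transcription factor genes Pou4f1, Lhx4, Isl2 and Ebf3 rose here too. Of 14707 genes 3308 were called, 1334 higher and 1974 lower, of which 1285 changed at least 2-fold (380 higher and 905 lower). In 3925 genes (26.7%) the ranges of the groups did not overlap, where chance gives 2.86% with preparation ignored.

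Pou4f1 was at 4.71 ± 0.42 (SE, adjusted p = 3.16e-06), Lhx4 at 4.78 ± 0.44 and Isl2 at 4.52 ± 0.46 on the log2 scale over Htt-25Q. Ebf3 was at 4.16 ± 0.38, Cdkn2a at 4.48 ± 0.51 and Ripk4 at 4.13 ± 0.49. Irs4 rose by 5.00 ± 0.54, or 5.86 without Htt-25Q 1, and Hoxb13, a posterior Hox gene, by 4.0 ± 0.73, or 3.28 without Htt-72Q 4. Hoxd8, another Hox gene, had 0 counts in the 4 Htt-25Q libraries and 144 counts over the Htt-72Q libraries, which puts it at least 70.9-fold higher in Htt-72Q when 3 counts over the group are taken as the limit in Htt-25Q. Among the largest falls were Gpr6 at -4.18 ± 0.26 (adjusted p = 1.52e-07), Hrh3 at -3.48 ± 0.26 and Rgs4, a brake on G protein signalling, from 764 ± 357 to 71.7 ± 39.0 CPM (-3.41 ± 0.46). Others were St3gal1 at -3.35 ± 0.28, Cd93 at -3.32 ± 0.40, Robo3, an axon guidance receptor gene, at -3.20 ± 0.33, Nwd2 at -3.15 ± 0.16 and Syt10, a synaptotagmin gene, at -3.04 ± 0.26.

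Of 20 excitatory neuron markers 16 fell, 1 rose and 3 did not pass, the same adjusted over the list alone in falls and rises (median -1.03, adjusted p = 1.9e-07, and adjusted p = 0.0453 with an estimated correlation). Mef2c changed by -2.14 ± 0.13 and Lmo4 by -1.94 ± 0.10. The p53 list kept its call with an estimated correlation as well (adjusted p = 0.000108 and 0.0453). There 11 of 23 rose, 1 fell and 11 did not pass, 13 and 2 adjusted over the list alone, with Perp at 1.40 ± 0.16 and the polymerase gene Polk at 1.87 ± 0.29. Inhibitory markers fell (10 of 21 lower, 0 higher, 11 not passing, 10 lower and 1 higher adjusted over the list alone; adjusted p = 0.00075, adjusted p = 0.303 with an estimated correlation), with Gad1 at -1.42 ± 0.25. Immediate early genes fell, with 9 of 27 lower, 0 higher and 18 not passing, 9 adjusted over the list alone (median -1.42, adjusted p = 0.000468, adjusted p = 0.562 with an estimated correlation). The median was -0.65 with the block by preparation (adjusted p = 1.18e-05), and within preparations 22, 24 and 27_1 the list score differed by -0.71, -0.74 and -1.04. Preparations 27 and 27_1, where immediate early genes stood higher, hold 2 of the 4 Htt-25Q libraries and 1 library of each other group. Npas4, an activity-induced transcription factor, was at -2.44 ± 0.57 and Egr3, another, at -2.51 ± 0.61 or -3.62 without Htt-72Q 4. Of 22 neuropeptide and granin genes 11 fell, 0 rose and 11 did not pass, 13 adjusted over the list alone (adjusted p = 0.000131, adjusted p = 0.399 with an estimated correlation), with the granin gene Scg2 at -1.42 ± 0.28.

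Among synaptic lists, 14 of 25 postsynaptic density genes fell, 1 rose and 10 did not pass (17 and 1 adjusted over the list alone; adjusted p = 8.37e-07, adjusted p = 0.349 with an estimated correlation). Camk2b was at -1.72 ± 0.12. Of 24 glutamate receptor genes 11 fell and 13 did not pass (13 lower adjusted over the list alone; adjusted p = 2.6e-05, adjusted p = 0.349 with an estimated correlation), with Gria1 at -1.51 ± 0.14. Of 14 GABA receptor genes 9 fell and 5 did not pass (9 adjusted over the list alone; adjusted p = 0.000125, adjusted p = 0.349 with an estimated correlation). Of 33 channel genes 18 fell and 15 did not pass (19 adjusted over the list alone; adjusted p = 2.12e-07, adjusted p = 0.349 with an estimated correlation). Synaptic vesicle genes fell in 8 of 25, with 17 not passing and 9 lower adjusted over the list alone (adjusted p = 0.00474, adjusted p = 0.547 with an estimated correlation, 0.0627 with the block by preparation). Of 25 striatal signalling genes 14 fell, 1 rose and 10 did not pass (17 and 1 adjusted over the list alone; adjusted p = 1.96e-06, adjusted p = 0.222 with an estimated correlation). Of 31 proteasome genes 14 rose and 17 did not pass (26 adjusted over the list alone; adjusted p = 1.9e-07, adjusted p = 0.349 with an estimated correlation), with Psma5 at 0.82 ± 0.21. Of 28 autophagy and lysosome genes 8 rose, 1 fell and 19 did not pass (9 and 1 adjusted over the list alone; adjusted p = 0.00401, adjusted p = 0.238 with an estimated correlation), with Ctsd at 0.90 ± 0.13. The respiratory chain list was called with 1 of 36 members higher and 0 adjusted over the list alone (adjusted p = 0.00662, adjusted p = 0.69 with an estimated correlation, 0.0841 without Htt-72Q 3). Interferon genes were called with 3 of 9 higher and 1 lower, the same adjusted over the list alone (median 0.67, or 0.26 with the block by preparation; adjusted p = 0.0406, adjusted p = 0.238 with an estimated correlation, 0.0569 without Htt-72Q 4). Cholesterol genes were called with 7 of 25 lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.0491, adjusted p = 0.717 with an estimated correlation). That call ended without Htt-72Q 1 (0.243), Htt-72Q 3 (0.0518), Htt-25Q 3 (0.180) or Htt-25Q 4 (0.0852).

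Lists that did not pass against Htt-25Q were proliferation (adjusted p = 0.101), REST targets (0.158), the unfolded protein and stress response (0.225), fibroblast and mural markers (0.265), and neural progenitors (0.319). The others were ribosomal proteins, mitochondrial import and NF-kB genes (0.321 each), heat shock (0.434), astrocytes (0.518), mitochondrial messenger RNAs (0.596), long non-coding RNAs (0.686), HTT-interacting genes (0.718) and oligodendrocytes (0.804). Proliferation passed without Htt-25Q 1 (0.0440) or Htt-72Q 3 (0.0417), and REST targets without Htt-25Q 1 (0.0453). Fry ended 3 of the list calls against Htt-25Q, among them that of immediate early genes (0.0671), and called REST targets (0.0283). With only the libraries of class B, which hold 1 Htt-25Q library whose spread is taken from the other groups, this comparison called 1531 genes, and with class and preparation together as terms 1400, of which 1317 were called in the same direction as above. Leaving out 1 library ended the calls of 13 of 106 named genes, among them Tnfaip3 (0.88, adjusted p = 0.0719 without Htt-25Q 4) and Vim (0.39, adjusted p = 0.164 without Htt-25Q 4).

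**Figure D3:**
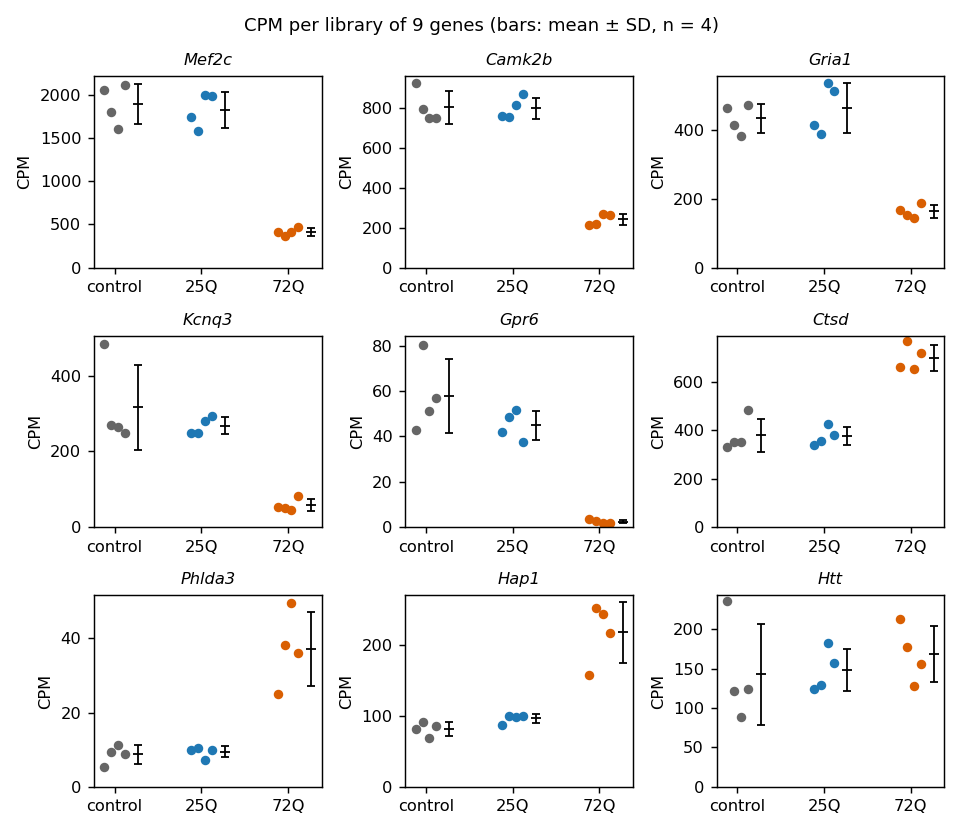
TMM-scaled CPM of 9 genes per library on axes from 0, with each point a library and bars for mean ± SD (n = 4). Camk2b lies at 242 ± 28.3 CPM in Htt-72Q and 805 ± 83.2 CPM in control vector (SD, n = 4), and Ctsd at 700 ± 53.5 and 379 ± 69.3 CPM.

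Htt-25Q against control vector asks what exon 1 with the short repeat does on its own. The edgeR quasi-likelihood test called 0 of 14707 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 it gave 129 genes (0.877%), or 603 (4.10%) with the block by preparation and 1039 (7.07%) with 27 and 27_1 as 1 preparation, and DESeq2 and limma voom also called 0. Groups without a difference would give a share of about 0.05, so the fit without a block was conservative here. The fits with either block also called 0. The genes with the smallest p were Plxnb3, a semaphorin receptor gene, at -0.97 ± 0.29, and Agap3 at -0.43 ± 0.13. They were followed by Thsd4 at -0.52 ± 0.17, Gpr17, a receptor of oligodendrocyte precursors, at -0.60 ± 0.20 and Gpr153 at -0.48 ± 0.16, with an adjusted p of 1 each. Non-overlapping ranges occurred in 146 genes (0.993%), where chance gives 2.86% with preparation ignored.

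Camera called 6 lists for Htt-25Q against control vector, with 0 called members in each and 0 adjusted over the list alone. These were immediate early genes (median 0.64, adjusted p = 2.04e-05), neuropeptides (0.31, 0.000168), long non-coding RNAs (0.24, 0.0361) and ribosomal proteins (0.04, 0.0443), higher, and oligodendrocyte markers (-0.20, 0.000857) and synaptic vesicle genes (-0.13, 0.0409), lower. With an estimated correlation the adjusted p was 0.985 for each, and fry called 0 lists. Preparations 27 and 27_1 hold 2 of the 4 Htt-25Q libraries and 1 control library. The median of immediate early genes was 0.16 with the block by preparation (adjusted p = 0.0264), and within preparations 22, 24 and 27_1 their score differed by 0.05, 0.17 and 0.15. Leaving out 1 library ended 5 of these calls. Immediate early genes stood at an adjusted p of 0.0714 without Htt-25Q 3 and a median of 1.30 without control vector 4, and oligodendrocyte markers at 0.163 without control vector 3. Long non-coding RNAs stood at 0.520 without control vector 3, 0.0541 without Htt-72Q 3 and 0.127 without Htt-25Q 3. Ribosomal proteins stood at 0.273 without control vector 1, 0.142 without Htt-25Q 1, 0.119 without Htt-25Q 2, 0.0636 without Htt-72Q 4 and 0.0820 without Htt-25Q 3. Synaptic vesicle genes stood at 0.941 without control vector 1, 0.872 without Htt-25Q 1, 0.487 without Htt-25Q 2, 0.0541 without Htt-72Q 3, 0.153 without control vector 4 and 0.0570 without Htt-72Q 4. The count of lists rose to 10 without control vector 1 and to 11 without Htt-25Q 4. Lists outside these 6 passed in some fits without 1 library. Without control vector 1 these were the stress response (0.00527), proteasome (1.11e-05), respiratory chain (8.09e-07), mitochondrial messenger RNA (0.0293), cholesterol (0.000585) and proliferation (0.00640) lists. Channels passed without control vector 2, control vector 3, Htt-25Q 3 or Htt-25Q 4 (0.00128 to 0.0385) and astrocyte markers without control vector 2, Htt-25Q 3 or Htt-25Q 4 (0.0120 to 0.0303). Glutamate receptors passed without control vector 3 (0.0239), mitochondrial import without control vector 4 (0.0149) and postsynaptic density genes without Htt-25Q 3 (0.0346) or 4 (0.0247). Mitochondrial messenger RNAs passed also without Htt-25Q 3 (0.0318), and cholesterol and proliferation genes without Htt-25Q 3 (0.0120 and 0.0318) or 4 (0.0247 and 0.00585). With the block by preparation the oligodendrocyte (0.0647) and long non-coding RNA (0.266) calls ended, synaptic vesicle genes had a median of -0.25 and ribosomal proteins of 0.19, and glutamate receptors (0.00893), postsynaptic density (0.0238), channels (9.88e-05), mitochondrial import (0.0497) and astrocyte markers (0.00724) were called.

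The genes called in Htt-72Q were largely shared between its comparisons: 2757 were called against both control vector and Htt-25Q, 1053 higher and 1704 lower, where independent lists would share 126 and 271, and 0 were called in opposite directions. With 2 of the 4 Htt-72Q libraries for each comparison, 1404 genes on average were called in both (1321 to 1555). Between the comparisons of Htt-72Q and Htt-25Q against the same control vector libraries, log2 fold changes correlated across genes at r = 0.193. Simulated groups without a change gave 0.0486. They were drawn around the mean level of those same control libraries, so the simulation left out the deviation of the controls that both comparisons share. Its baseline is therefore too low. The covariance exceeded the simulated one by 0.0306, and by 0.0602 with the block by preparation, but against such a baseline neither excess shows a shared response. With 2 of the 4 control libraries for each comparison the covariance was -0.0189 (range -0.0455 to 0.0106). Genes are not independent replicates, and no gene was called in both of these comparisons because 0 were called in Htt-25Q.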

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

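The values here were picked out by a rule fixed in advance. A fit without control vector 1 and Htt-72Q 3, the libraries farthest from their groups, was chosen after the data were seen. In a group of 4 libraries, a value stands apart when its gap to the nearest other library exceeds Dixon's critical share of the range of the group. Chance marks about 1 in 20 groups: 29 of 495 groups of values stood apart, where 24.8 would by chance. Control vector 1 and Htt-72Q 4 held the most, 7 each.

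Among library measures, mitochondrial ribosomal RNAs held 14.2% of counts in control vector 3, against 6.71 to 7.80% in the other control libraries. Among list scores, in mean log2 difference from control vector, immediate early genes stood at 1.41 in control vector 4 (others -0.62 to -0.34), and inhibitory neuron markers at 0.19 in control vector 3 (others -0.07 to -0.06). Striatal signalling genes stood at -0.65 in Htt-72Q 4 (others -1.09 to -1.05). In Htt-72Q 3, synaptic vesicle genes stood at -0.74 (others -0.46 to -0.43), mitochondrial messenger RNAs at 0.49 (others -0.44 to -0.29) and astrocyte markers at -0.28 (others -0.0032 to 0.04).

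Among named genes, the CPM of the library that stood apart is given first. In control vector 1, St3gal1 was at 58.8 (others 28.4 to 31.2), Kcng1 at 53.7 (7.42 to 9.63), and Kcnq3 at 483 (247 to 269). In the same library Rorb was at 180 (108 to 114), Psma2 at 83.7 (124 to 134), Timm22 at 13.7 (25.5 to 28.4) and Mvd at 116 (199 to 206). Cryab was at 3.53 in control vector 2 (5.40 to 5.70), Robo3 at 4.19 in control vector 3 (6.43 to 6.88) and Gad1 at 150 in control vector 4 (108 to 114). In Htt-72Q 4, Pgr15l was at 6.43 (3.27 to 3.48), Isl2 at 2.23 (4.79 to 5.58), Perp at 14.0 (15.97 to 16.4), Aen at 84.4 (101 to 104) and Egr3 at 10.1 (1.64 to 1.99). Sst was at 16.2 in Htt-25Q 1 (10.99 to 11.7), Mvd at 136 (179 to 186), Foxp1 at 121 (98.2 to 102) and Hap1 at 87.4 (98.2 to 99.9) in the same library. In Htt-25Q 3, Syn2 was at 280 (249 to 250) and Phlda3 at 7.22 (9.97 to 10.5).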

How the results depend on the processing

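The fits with library class, equal depth, GC and length offsets, or without control vector 1 and Htt-72Q 3 were chosen after the data were seen. Genes called for Htt-72Q against control vector stayed within 1.5 times the reported count under each of 22 settings, from 2288 to 5004, and from 2671 to 3265 leaving out 1 library. Against Htt-25Q, 20 of 22 did so and leaving out 1 library gave 2293 to 3902. The exceptions were 1400 with library class and the block by preparation and 1531 with libraries of class B only, a fit of 6 libraries with 1 of Htt-25Q, whose spread is taken from the other groups. Htt-25Q against control vector called 0 genes by edgeR, DESeq2 and limma voom in these settings and in each fit without 1 library (129 genes at an unadjusted p under 0.05 in the reported fit, 603 with the block by preparation).

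Lists called fell to 0 for Htt-72Q against control vector, 0 for Htt-25Q against control vector and 2 for Htt-72Q against Htt-25Q with an estimated correlation. The estimate was 0.467 for proteasome genes, 0.429 for channels, 0.0734 for excitatory neuron markers and 0.0155 for p53 targets, against the preset 0.01. Interferon genes, at -0.0761, lost their call as well. The small p values of camera in the reported fits depend on the preset setting. The size of the correlation alone does not account for the lost calls. Against control vector, p53 targets and interferon genes lost theirs with estimates near or below the preset, and the cause was not tested. Fry gave 0 for Htt-25Q against control vector, and library class with the block by preparation gave 12; the cause was not tested. Leaving out 1 library gave 14 to 19, 4 to 11 and 15 to 19 lists. In class B alone the synaptic vesicle list for Htt-25Q against control vector reversed to a median of 0.21 (adjusted p = 0.000498), where the lone Htt-25Q library is assumed to vary like the others; the cause was not tested.

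For Htt in Htt-72Q against control vector the log2 fold change passed the threshold in class B alone (0.55), with GC and length offsets (0.59, or 0.60 with the block), and without control vector 1 and Htt-72Q 3 (0.70). It passed also against Htt-25Q with the offsets and block (0.42); the cause was not tested. Leaving out 1 library gave 0.047 to 0.59 and, for Htt-25Q against control vector, -0.14 to 0.41 and, for Htt-72Q against Htt-25Q, 0.050 to 0.30. The excess covariance of the comparisons against control vector (0.031) was 0.060 with the block, both over a simulated baseline that is too low. With 2 of the 4 control libraries for each comparison the covariance was -0.019, and the cause of these differences was not tested. The block by preparation ended the calls of Creld2 (adjusted p = 0.101), Ndrg2 (0.113), Hes1 (0.0707) and Vim (0.0758) against Htt-25Q and called oligodendrocyte markers against control vector (0.0246). With the list calls given in the results, it changed no other call of a named gene or list. Scaling by other factors moved the median of all genes by at most 0.06. Upper-quartile scaling gave 1735 genes higher and 1778 lower against control vector, and 1573 and 1790 against Htt-25Q. The excess of lower genes stayed but shrank, so its size depends on the scaling. Lower depth in Htt-72Q limits genes near 0 counts.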

Other observations

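Tests of library class, of depth, of the share of excitatory neurons, of homeobox genes and of genomic span were chosen only after the result was seen.

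Hox and other Polycomb-target developmental genes were mostly too low for the filtered fit, which held 3 of 40. In a fit without the filter, 33 of 40 had a count, and 12 rose and 0 fell in Htt-72Q against control vector, and 12 adjusted over the list alone. Against Htt-25Q 14 rose and 0 fell, and 18 rose adjusted over the list alone, whereas Htt-25Q against control vector gave 0. Most of these genes stood near 0 CPM in control vector and Htt-25Q, so a fall could hardly be called. Of 4233 protein-coding genes other than homeobox genes, with a mean below 0.3 CPM outside Htt-72Q, 135 rose and 12 fell against control vector. Isl1, a LIM homeobox gene, stood at 0.803 ± 0.325 CPM in Htt-72Q (SD, n = 4) against 0.0149 in control vector (adjusted p = 0.000419). Isl1 was chosen after its values were seen. Onecut1 rose by 2.10 ± 0.44 against control vector on the log2 scale. Hoxa9, among the 12, averaged 7.11 ± 13.8 CPM in Htt-72Q, a spread larger than its mean. The same held for Hoxc8 (0.796 ± 1.40 CPM), Hoxc5 (0.394 ± 0.756) and Hoxc10 (0.471 ± 0.545), also among the 12. These were named after their values were seen. Of microglia (19 with a count), endothelial (14) and red blood cell genes (8), 0 were called by edgeR in any comparison.

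Genomic span was not among the lists fixed in advance. The mean log2 level of the sixth of genes spanning 94.9 kb or more, minus that of the shortest sixth and relative to control vector, was -0.41 ± 0.16 in Htt-72Q, 0 ± 0.31 in control vector and -0.13 ± 0.068 in Htt-25Q (SD, n = 4). The exact permutation p was 0.0286 for Htt-72Q against each, the smallest that 4 against 4 can give, and 0.657 for Htt-25Q against control vector. These p values hold only if libraries can be exchanged freely, but those of 1 preparation are alike. Control vector 1 stood at 0.44, and the other 3 control libraries had a mean of -0.15. Of the longest sixth 31.9% were lower and 5.64% higher in Htt-72Q against control vector, compared with 8.37% lower and 10.2% higher in the shortest sixth. Against Htt-25Q, 28.3% of the longest and 9.27% of the shortest were lower. Fos, an immediate early gene, stood at 81.9 to 102 CPM of the library total in the 4 libraries of preparations 27 and 27_1 and at 4.71 to 13.4 CPM in the other 8. Arc stood at 18.6 to 30.2 and 3.36 to 9.57 CPM, and Junb at 50.85 to 76.6 and 7.66 to 21.1 CPM. The ranges overlapped for Npas4 (4.64 to 21.2 and 1.15 to 7.535 CPM) and Egr3 (10.4 to 36.1 and 1.725 to 12.4 CPM). Control vector, Htt-25Q and Htt-72Q are all among preparations 27 and 27_1.

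As to the number of genes called for Htt-72Q, the 8 libraries of a comparison were split into 4 and 4 in 35 ways. Of these, 1 called as many as the real 3411 against control vector (the highest other called 0) and 1 as many as the real 3308 against Htt-25Q (highest other 0). That share is under 0.05 only if libraries can be exchanged freely, but those of 1 preparation are alike. The 8 splits that part as many preparation pairs (highest other 0 in each, 4 of them exchanging 1 library) are too few for a share under 0.05. The splits alone therefore cannot exclude chance. With library class as a covariate 96.4% and 84.5% of the 3411 and 3308 calls stayed in the same direction, and after thinning to equal totals 91.9% and 91.5%, which argues against class or depth as the whole cause. With class and preparation together, a fit of 4 residual degrees of freedom, 92.7% and 39.8% stayed called, and for those against Htt-25Q the median log2 fold change in the called direction went from 0.83 to 0.75 and the median SE from 0.18 to 0.22, with 3307 of 3308 in the same direction. For Htt-25Q against control vector the real count of 0 is one that any split reaches (35 of 35, highest other 86), so the splits say nothing there, and chance cannot be excluded for the number of lists: 6 of 35 splits were as large as the real 16 against control vector (highest other 20), 33 for the real 6 in Htt-25Q (highest other 17) and 4 for the real 16 against Htt-25Q (highest other 17), though for Htt-72Q the others as large exchange 1 library and so keep part of the real grouping, while splits that exchange 2 reach at most 14 and 12 lists. For the genes, an effect of Htt-72Q on the neurons remains a hypothesis, found and tested on the same libraries.

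As to the fall of excitatory neuron markers, a lower share of excitatory neurons would raise inhibitory and astrocyte markers alike. The first test, on the inhibitory minus astrocyte score, gave exact permutation p values of 0.0571 against control vector and 0.0286 against Htt-25Q and so did not exclude it. A second, added after the first was seen, found the inhibitory score itself lower in Htt-72Q than in each other group (-0.49 ± 0.25 against 0 and 0.08, larger exact two-sided p 0.0286, the smallest that 4 against 4 can give), which argues against that share as the whole cause. For a lower share of all neurons, the values met the limit set in advance against it. Of 25 pan-neuronal genes 13 fell, with a median of -0.39 and an interquartile range of -0.57 to -0.22. The median of the excitatory markers was -0.92. Such a loss would also raise astrocyte markers, but their score was -0.06 ± 0.15 in Htt-72Q, 0 ± 0.12 in control vector and -0.08 ± 0.17 in Htt-25Q (SD, n = 4). Progenitor markers had a median of 0.17 against control vector, with 0 of 17 called. The pan-neuronal, astrocyte and progenitor values argue against a lower share of all neurons as the whole cause, while a part stays open. The proliferation list was called higher against control vector (median 0.31, camera adjusted p = 0.0167, 0.267 with an estimated correlation). Against Htt-25Q it was not called (camera adjusted p = 0.101). How much of the fall is regulation within neurons stays open, and since the second test was chosen after the first did not pass, its p is weak evidence. Both permutation tests also ignore preparation, although libraries of 1 preparation are alike.

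As to the rise of developmental genes near 0 CPM, summed over 133 homeobox genes silent in the other groups, Htt-72Q held 53.4 ± 6.0 CPM (SD, n = 4) against 4.98 and 6.01. By contrast, the sum of 1020 olfactory receptor genes was 7.23 ± 2.70 CPM in Htt-72Q against 4.89 and 4.96. That is a log2 ratio of at most 0.56, against 3.42 and 3.15 for homeobox genes. The homeobox genes were picked for a mean below 0.3 CPM in the other groups and the olfactory genes were not, which can widen this gap. The small rise of the olfactory genes argues against genomic DNA or background reads as the whole cause. Of 15 markers of spinal cord or peripheral neurons with a count, 2 rose against Htt-25Q (Slc18a3 and Slc6a5) while Slc18a3 and Th rose and Dbh fell against control vector (named after their values were seen), and Prph, their abundant neurofilament gene, stood at 8.56 ± 1.25 CPM against 10.7 and 11.1, but only 7 of 15 reached 1 CPM in any group and the level of Prph would hide a small share, so such cells stay open, although the values met the limit set in advance against them. Silent homeobox genes rose in 30 of 110 and other silent protein-coding genes in 149 of 4233 against Htt-25Q (one-sided Fisher exact p = 1.29e-17, the larger of 2, and 0.0882 in 1 of 4 level ranges), but homeobox genes were chosen after some were seen to rise, so whether the rise is particular to them stays open. Loss of silencing of such genes is a candidate explanation that counts of RNA cannot test.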
